A study of Mus musculus with 64 samples.

How the data were processed

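The deposited table holds 1 raw count per gene and library for 64 libraries of sorted mouse microglia, in 12 groups by genotype, treatment and age group. Per the labels the RNA was made into libraries with a stranded total RNA kit and read on 2 sequencer models, and the authors list bcl2fastq 2.20, Trim Galore 0.6.7, STAR 2.6.1d, Salmon 1.5.2 and the build GRCm38. The labels do not say which of these tools produced the deposited counts. The labels assign the sequencers by kind of sample and not per library, and this assignment does not follow the batches seen in the counts. Dose, day and sex are not stated, nor whether replicates are separate animals. Sex was read from 4 Y-linked genes (23 female and 41 male libraries).

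The table has 45708 genes, of which 12089 have 0 counts in every library. Total counts run from 2.7 to 24 M with a median of 11.9 M. The floor for a gene with 0 counts was set at 3 counts per library, or 0.748 counts per M in the KO cuprizone library without Uqcrfs1 counts. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 18413. Scaling was by TMM. The planned test was edgeR 4.0.16 (glmQLFit and glmQLFTest) over all libraries with 1 mean per group and no covariate, two-sided, in 17 contrasts, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Controls at depletion and repopulation are the mean of Het and WT. The contrasts, the 24 gene lists, the naming rule and the alternatives not said below to be added later were chosen before the data were examined.

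The counts then showed batches. Libraries were divided by the share of counts on Gm26917 and Yam1 (below or above 1%) and, above it, by total counts (over 15, under 5.5 M, or between). The next fit used 1 mean per group and batch and compared groups inside batches, except for cuprizone. Another fit did the same on only the libraries compared, so that the spread of other groups does not enter. Both were chosen after the data were seen, and the within-batch fit gives the values in the report, with the counts of the planned fit and of that last fit beside them. Adjusted p values are Benjamini-Hochberg values of the within-batch fit unless another is named. Old and adult Het were compared among deep libraries, and cuprizone with the middle-depth naive libraries, which differ from it in depth.

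Gene lists were tested with camera of limma 3.58.1 on log2 counts per M (prior count 2) with a preset correlation of 0.01, adjusted over the 24 lists within a contrast. Camera with an estimated correlation and fry were run beside it. A count adjusted over the list alone repeats the adjustment on the members of that list. The lists cover complex III without Uqcrfs1, complex I, mitochondrial DNA genes, ATF4 and integrated stress response, glycolysis, homeostatic and injury-associated (DAM) microglia, cholesterol synthesis and efflux, lysosome, interferon, antigen presentation, cell cycle, cytokines and NF-kB, dissociation stress, border-associated macrophages, monocytes, neutrophils, lymphocytes, oligodendrocytes, astrocytes, neurons, endothelial cells and red blood cells. They were written from general knowledge, and mt-Cytb is the 1 gene held by 2 of them.

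Genes were named by rule: Uqcrfs1, and of other genes the 5 called ones with the largest positive and the 5 with the largest negative log2 fold change at a mean log2 CPM of at least 3 (without Gm-numbered and Rik symbols), and up to 4 called members of each list with the smallest p. Other members of a list could be named with their values. Errors are standard errors of the log2 fold change.

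The fits were tested on simulated data in which 200 of 18413 genes were changed. The changed genes were drawn only from genes above a minimum mean count, so the recovery rates do not cover genes with lower counts. In naive KO against Het the planned fit recovered 63% of 2-fold and 92% of 4-fold changes with 3 false calls, and the fit within batches 71% and 99% with 7. For cuprizone the fit within batches recovered 46% and 88% (4 false), for repopulation 58% and 87% (5), for depletion 27% and 78% (5) and for old against adult 17% and 77% (3), where the planned fit made 298 false calls. The simulated counts used the spread of the within-batch fit as a trend shared by all groups. They therefore cannot show false calls that arise where groups differ in spread.

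Alternatives were DESeq2's size factors in edgeR, DESeq2 1.42.0 (Wald test), no filter on low counts, only the groups compared, the replicate number as a block, 2 surrogate variables (sva 3.50.0) and each library left out in turn from groups of 2 to 5. Sex as a covariate, counts thinned to the smallest total, single batches, leaving out libraries within batches, the replicate number as a block together with library batch and old Het without replicate 3 were added after the data were seen. A selection of Het cuprizone libraries by their Fos level was also run and then dropped after its result was seen, because libraries must not be chosen by a measured outcome; no value from it is reported. R 4.3.3 was used. Expression of the 2 transgenes in the table was read as counts per M and was not tested.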

Results

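RNA was sequenced from microglia, the resident macrophages of the brain, sorted from whole mouse brain by CD11b and CD45. RISP, encoded by Uqcrfs1, is the Rieske iron-sulphur protein of respiratory complex III, and the libraries are labelled KO, Het or WT for it. The 64 libraries form 12 groups. Naive adults gave 13 KO, 13 Het and 5 WT libraries, and old naive mice 3 Het libraries. Cuprizone, a copper chelator that kills oligodendrocytes and strips myelin, gave 6 KO and 4 Het libraries. PLX3397, an inhibitor of the receptor CSF1R that removes microglia, gave 2 KO, 2 Het and 4 WT libraries at depletion and 4 KO, 4 Het and 4 WT libraries at repopulation. The labels give no dose or day and do not say whether replicates are separate animals. Total counts ran from 2.7 to 24 M per library, with a median of 11.9 M.

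Uqcrfs1 (ENSMUSG00000038462, GRCm38 chr13:30540308-30545362, minus strand) was lower in every group labelled KO than in its controls. Naive WT libraries held 34.4 to 43.9 counts per M (CPM). Over all batches naive Het libraries held 9.16 to 37.7 CPM and naive KO libraries 1.24 to 9.32 CPM. In the batch that holds the WT libraries, the ncRNA-poor one described below, naive Het held 19 to 37.7 CPM and naive KO 5.33 to 9.32 CPM. Under cuprizone the ranges were 10.3 to 12.9 CPM in Het and 0 to 1.47 CPM in KO, where 1 library had 0 counts, which allows up to 0.748 CPM by counting error alone. After PLX3397 they were 30.6 to 51.8 (Het), 36.3 to 62.1 (WT) and 9.1 to 13.5 CPM (KO) at depletion, and 29 to 35.9, 46.8 to 65.5 and 6.57 to 10.9 CPM at repopulation. Old Het libraries held 7.01 to 13.1 CPM. The KO and Het ranges did not overlap inside any batch of libraries. Within batches Uqcrfs1 fell in naive KO against Het (log2 fold change -2.20 ± 0.15 SE, adjusted p = 3.12e-16) and against WT (-2.37 ± 0.23, adjusted p = 6.63e-10), and in KO under cuprizone (-4.00 ± 0.33), at depletion (-1.96 ± 0.32) and at repopulation (-2.30 ± 0.24). Naive Het did not pass against WT in the ncRNA-poor batch (-0.64 ± 0.23, adjusted p = 0.41). There Het replicate 1 held 37.7 CPM, inside the WT range, and Het 2 to 4 held 19 to 23.1 CPM, below it. The Het range also lay below the WT range at repopulation, and the 2 ranges overlapped at depletion. The planned fit over all 64 libraries, without batches, gave -1.93 for naive KO against Het.

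**Figure D1:**
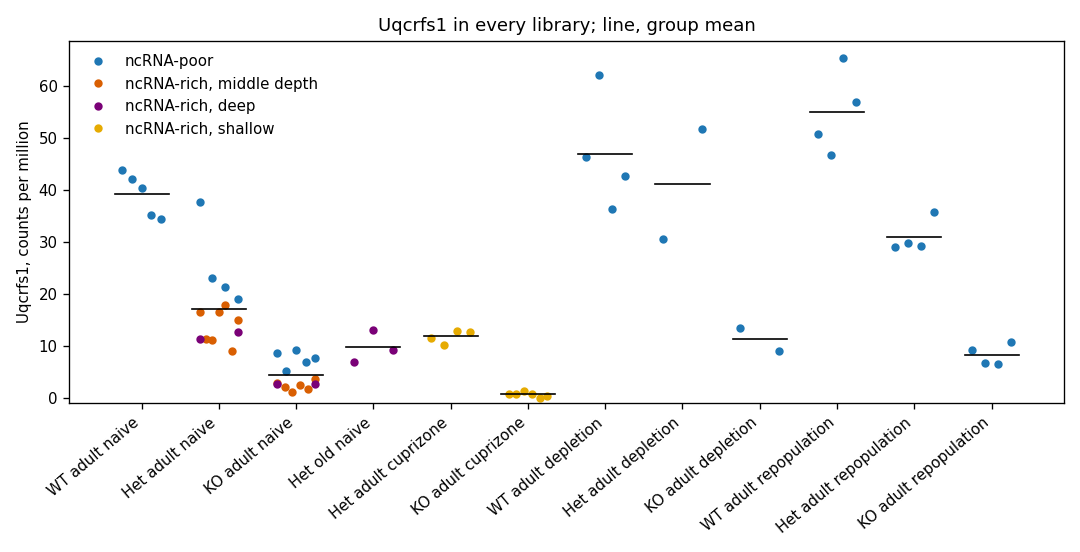
Uqcrfs1 in each of the 64 libraries (counts per M, TMM-scaled) by group, with the batch of each library marked. Naive KO libraries lie between 1.24 and 9.32 over all batches. In the ncRNA-poor batch naive KO libraries lie between 5.33 and 9.32 and naive WT libraries between 34.4 and 43.9.

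The libraries fall into batches that the labels do not name. Gm26917 and Yam1, 2 noncoding transcripts, took 0.069 to 0.28% of counts in 34 ncRNA-poor libraries and 2.216 to 13.54% in 30 ncRNA-rich ones, and the first principal component (46.7% of variance) separated these sets. The ncRNA-poor set holds naive KO replicates 1 to 5, Het 1 to 4, every WT and every PLX3397 library. The ncRNA-rich set divides by depth into 7 deep libraries (15.9 to 24 M: naive KO and Het replicates 12 and 13, and old Het), 13 of middle depth (6.4 to 11.7 M: KO 6 to 11 and Het 5 to 11) and 10 shallow ones (2.7 to 5.1 M: cuprizone only). Comparisons are therefore given within batches, chosen after the counts were seen, with the planned pooled counts and with a fit of only the libraries compared. Of 187 calls of gene lists by camera 30 held with an estimated correlation between genes, and 6 of these also in the libraries compared alone. They were ATF4 genes in KO against Het naive and in KO against controls at repopulation, and border macrophage and lysosome genes in controls at depletion against naive. The others were interferon genes in repopulated against naive KO and in repopulation against depletion in controls. Cuprizone has a depth batch of its own, so cuprizone and that batch cannot be told apart in any comparison with naive mice. Inside it Het 3 and 4 and KO 5 and 6 held 2.216 to 2.49% on the 2 transcripts, against 3.618 to 6.698% in the other cuprizone libraries. Their mean log2 CPM of cytokine and NF-kB genes was 5.911 to 6.796, against 3.826 to 5.095. This division was not in the model and enters KO against Het under cuprizone. Among the ncRNA-poor naive libraries KO 5, Het 1 to 4 and WT 5 follow each other in sample order. KO 1 to 4 and WT 1 to 4 stand apart from them. That order was not in the model either, and it enters Het against WT and KO against Het in that batch.

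The loss of RISP in naive adults was examined first (13 KO against 13 Het libraries). Within batches 3106 of 18413 genes passed, 1699 higher and 1407 lower, or 1428 and 1696 with DESeq2's size factors. The planned pooled fit called 1760 (942 higher, 818 lower) and the fit of the 26 libraries alone 2429 (1169 and 1260). Of 73 named genes past the threshold 72 also passed in that last fit. Within single batches the calls were 272 higher and 230 lower (ncRNA-poor), 1414 and 1117 (middle) and 64 and 41 (deep).

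Lox, a lysyl oxidase that crosslinks collagen, rose by 3.63 ± 0.29 (adjusted p = 5.79e-14). Atf5, a stress transcription factor, rose by 3.21 ± 0.21 (adjusted p = 1.55e-16), the muscle-type cytochrome oxidase subunit Cox6a2 by 2.89 ± 0.27, the angiogenic factor Vegfa by 2.58 ± 0.31 and the mitochondrial folate enzyme Aldh1l2 by 2.23 ± 0.27. The receptor Notch4 fell (-2.72 ± 0.53), with AC102815.1 (-2.44 ± 0.43, not called pooled), the AP-1 member Fosb (-2.29 ± 0.40), the orphan receptor Gpr165 (-2.15 ± 0.23) and Klf4 (-2.02 ± 0.28). Of 28 measured ATF4 and integrated stress response genes 18 rose, 1 fell and 9 did not pass, against 19 and 2 adjusted over the list alone. The folate enzyme Mthfd2 (2.16 ± 0.20), the amino acid transporter Slc7a5 (1.13 ± 0.11) and Phgdh of serine synthesis (1.04 ± 0.11) were among them, and camera's call held with an estimated correlation (adjusted p = 0.0069). In the ncRNA-poor, middle and deep batches Atf5 rose by 2.71 ± 0.35, 3.43 ± 0.31 and 3.62 ± 0.55, and in the ncRNA-poor batch KO replicate 1 held 12.3 CPM against 42 to 94.6 CPM in KO 2 to 5. Among mitochondrial DNA genes 12 of 13 rose (13 adjusted over the list alone), led by mt-Co1 (1.32 ± 0.14) and mt-Nd1 (1.02 ± 0.13), with camera at adjusted p = 3.86e-12 and adjusted p = 0.0565 with an estimated correlation. In the ncRNA-poor batch mt-Co1 was higher by 0.63 ± 0.24 and did not pass, against 1.52 ± 0.20 in the middle batch.

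Of 18 glycolysis genes 13 rose (14 and 1 lower adjusted over the list alone), such as Aldoa (1.06 ± 0.12), Tpi1 (1.11 ± 0.15) and Pgam1 (0.90 ± 0.11), with camera's call lost at adjusted p = 0.0537 with an estimated correlation. Complex I nuclear genes gave 16 of 36 higher (19 adjusted over the list alone), Ndufa6 first (0.77 ± 0.12), and complex III 5 higher and 1 lower of 15 (8 and 1), Uqcrh first (0.78 ± 0.12), with adjusted p = 0.18 and 0.156 with an estimated correlation. Injury-associated (DAM) genes gave 17 higher and 2 lower of 28 (the same adjusted over the list alone), such as the cathepsin Ctsb (0.76 ± 0.09) and the cystatin Cst7 (1.75 ± 0.22), while 6 of 19 homeostatic genes fell (9 adjusted over the list alone), such as Selplg (-0.47 ± 0.07) and Tgfbr1 (-0.34 ± 0.05), with adjusted p = 0.25 and 0.326 with an estimated correlation. Dissociation stress genes gave 14 of 18 lower (17 adjusted over the list alone) with a median of -1.16, and adjusted p = 0.0771 with an estimated correlation. Klf4 fell in the middle batch (-3.11 ± 0.41) and not in the ncRNA-poor batch (-0.71 ± 0.46, adjusted p = 0.53). Lysosome (9 higher and 1 lower of 21), cholesterol synthesis (4 and 1 of 19) and cell cycle genes (7 and 1 of 38) had higher medians of 0.17, 0.24 and 0.54, with adjusted p = 0.349, 0.18 and 0.247 with an estimated correlation. Cytokine and NF-kB genes (1 and 3 of 20), border-associated macrophage genes (0 and 1 of 12) and endothelial genes (0 and 1 of 11) had lower medians of -0.32, -0.51 and -0.54, with adjusted p = 0.477, 0.5 and 0.367 with an estimated correlation.

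Without a camera call were interferon (0 higher and 4 lower of 22), cholesterol efflux (2 and 2 of 13), antigen presentation (2 and 3 of 15, with median 0.01 but mean -0.16), monocyte (0 and 1 of 9, with median -0.12 but mean 0.01), neutrophil (1 and 0 of 12) and lymphocyte genes (0 and 1 of 13). The oligodendrocyte, astrocyte, neuron and red blood cell lists held 0 calls.

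**Figure D2:**
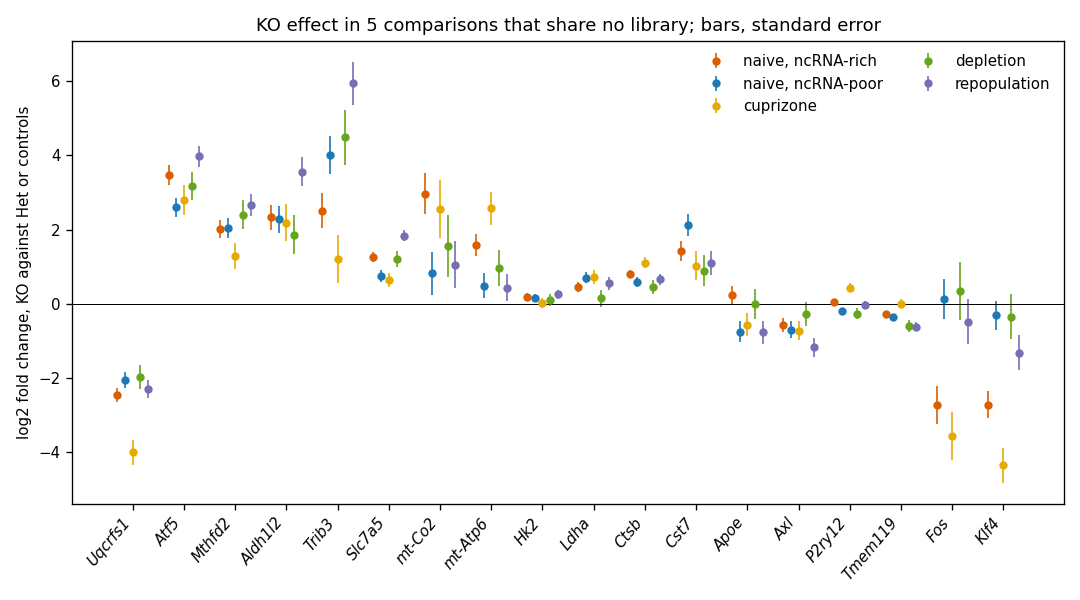
Log2 fold changes (within batch, with SE bars) of named genes in the comparisons of KO with its controls, with 1 point per comparison. Atf5 lies between 2.6 and 3.97 and Uqcrfs1 between -1.96 and -4.00 in the 5 comparisons that share no library.

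Against WT, in the 5 KO and 5 WT naive libraries of the ncRNA-poor batch, 356 genes passed (211 higher, 145 lower), against 5291 in the planned pooled fit and 154 from the 10 libraries alone. Leaving out 1 library gave 91 genes (without KO replicate 4) to 587 (without KO replicate 1). The count was 192 without KO 3 or 5 and 222 and 228 without WT 3 and 4. Of 30 named genes 16 kept their call in the 10 libraries alone, those given next among them, and 12 with each library left out in turn. The stress genes Aldh1l2 (2.54 ± 0.44), Atf5 (2.49 ± 0.32, adjusted p = 1.57e-06) and Mthfd2 (1.67 ± 0.32) rose with Cox6a2 (1.90 ± 0.40) and Cst7 (1.89 ± 0.35), and the stress kinase-like Trib3 rose by 3.53 ± 0.63. KO replicate 1 lay close to WT in Atf5 and Mthfd2, although its Uqcrfs1 was low (8.65 CPM). Its Atf5 was at 12.3 CPM (WT 9.08 to 11.5, KO 2 to 5 42 to 94.6) and its Mthfd2 at 21.9 CPM (WT 9.65 to 20.7, KO 2 to 5 58.6 to 82.8). The phospholipase Plbd1 (-2.09 ± 0.58), the chemokine receptor Ccr2 (-1.83 ± 0.47) and the class II antigen gene H2-Aa (-1.62 ± 0.39) fell. Of ATF4 genes 12 of 28 rose (15 adjusted over the list alone) and of glycolysis genes 11 of 18 (13 adjusted over the list alone), and both camera calls held with an estimated correlation (adjusted p = 0.00052 and 0.00292), though not in the 10 libraries alone (adjusted p = 0.248 and 0.216). In KO replicate 1 the mean log2 CPM lay inside the WT range for both lists, at 3.911 for ATF4 genes (WT 3.656 to 4.033, KO 2 to 5 4.751 to 5.396) and 6.992 for glycolysis genes (WT 6.897 to 7.015, KO 2 to 5 7.609 to 7.73). Mitochondrial DNA genes gave 2 higher of 13 (7 adjusted over the list alone), with adjusted p = 0.137 with an estimated correlation. Antigen presentation genes gave 4 lower of 15 (6 adjusted over the list alone) with adjusted p = 0.044 with an estimated correlation and 0.081 in the 10 libraries alone. Markers of other cells had lower medians too, at -0.84 (border macrophages, 1 lower of 12), -1.35 (monocytes, 1 lower of 9), -1.39 (lymphocytes, 0 of 13) and -1.13 (endothelial cells, 0 of 11). Their tests gave adjusted p = 0.217, 0.0261, 0.00223 and 0.0238 with an estimated correlation. The neuronal list had the lowest median (-1.62, 1 lower of 11, adjusted p = 0.374 with an estimated correlation), and oligodendrocyte genes went the other way (0.60, 0 of 11, no camera call). WT replicate 2 stood apart in border macrophage genes (mean log2 CPM 6.415, others 5.265 to 5.532).

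Het against WT gave 4 genes inside that batch (4 against 5 libraries) and 6699 in the planned pooled fit, where 9 of the 13 Het libraries and 0 WT libraries were ncRNA-rich. By Y-linked genes all 5 WT libraries and 1 of the 4 Het libraries in that batch were male. Sex and genotype are therefore hard to tell apart there. The cold-inducible RNA-binding gene Rbm3 (-1.49 ± 0.25, adjusted p = 0.00292) and Haghl (-1.32 ± 0.27) fell, and Rc3h1, which binds messenger RNA, rose by 0.64 ± 0.13. The count was 117 without WT replicate 5 and 2 without WT 1, 3 or 4. In sample order WT 5 stands with Het 1 to 4, apart from WT 1 to 4. Genotype and that order are therefore hard to tell apart too. The mean log2 CPM of dissociation stress genes was 7.596 in WT 5 (Het 7.551 to 7.737, other WT 6.268 to 7.077). That of complex I genes was 4.573 (Het 4.461 to 4.594, other WT 4.799 to 4.83). These 2 lists were chosen after their values were seen. AC102815.1 also rose; it lies outside the naming rule here and was chosen after its values were seen. With only the 9 libraries edgeR called 0 genes, with 2587 at an unadjusted p under 0.05. DESeq2 and surrogate variables, both over all 64 libraries, called 6971 and 3.

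Demyelination was examined next. In Het mice under cuprizone (4 against the 7 middle-depth naive libraries) the model over all libraries called 1702 genes (641 higher, 1061 lower, or 812 and 739 with DESeq2's size factors), the planned fit 2242, and the 11 libraries alone 343 (260 and 83), so that most calls rest on the spread of other libraries. The median gene lay at -0.157. The chaperones Hspa1b (5.71 ± 0.81, adjusted p = 3.14e-06) and Hspa1a (4.6 ± 0.65) rose, with Ece1 (3.07 ± 0.77), the chemokine Ccl4 (2.83 ± 0.60) and the stress phosphatase subunit Ppp1r15a (2.74 ± 0.48), and each passed in the 11 libraries alone. Lower were Rn7s6, a noncoding RNA (-3.30 ± 0.71), Hist1h1d (-2.55 ± 0.51), Syne2 (-2.52 ± 0.62), Tulp3 (-2.49 ± 0.53) and Nrd1 (-2.41 ± 0.58), which passed there too. Of 57 named genes 27 kept their call in the 11 libraries alone. Among DAM genes 5 of 28 rose (9 adjusted over the list alone), with the glycoprotein Gpnmb by 4.78 ± 0.66, the lipid carrier Apoe by 1.31 ± 0.30 and the growth factor Csf1 by 1.18 ± 0.31, and camera's call was lost at adjusted p = 0.743 with an estimated correlation. Of dissociation stress genes 9 of 18 rose (15 adjusted over the list alone, 11 in the 11 libraries alone), of cytokine and NF-kB genes 7 of 20 (14 adjusted over the list alone), such as Ccl3 (2.59 ± 0.56) and Nfkb2 (0.86 ± 0.16), and of ATF4 genes 7 of 28 (8), such as Ddit3 (1.40 ± 0.19), with adjusted p = 0.111, 0.153 and 0.153 with an estimated correlation. Astrocyte genes gave 4 lower of 11 (8 adjusted over the list alone), such as Aldoc (-3.40 ± 0.87), and neuronal genes 6 lower of 11 (8), with adjusted p = 0.153 and 0.111 with an estimated correlation. The homeostatic gene Tgfbr1 (-0.50 ± 0.09) and the sterol regulator Srebf2 (-0.57 ± 0.12) fell in the model and did not pass in the 11 libraries alone. Oligodendrocyte genes had a median of -1.66 with 2 lower of 11.

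In KO mice under cuprizone (6 against 6 middle-depth libraries) 1037 genes passed (354 higher, 683 lower), against 2293 planned and 66 in the 12 libraries alone, where 10 of 41 named genes kept their call. Those kept include Hspa1a (4.66 ± 0.68), Hspa1b (4.45 ± 0.80), Ddit3 (0.90 ± 0.18), Atf4 (0.61 ± 0.16), Rbm12 (-1.92 ± 0.35), Mobp of myelin (-3.56 ± 0.73) and Gfap of astrocytes (-3.98 ± 0.90). Gpnmb rose by 1.94 ± 0.53 and Ccl2 by 3.47 ± 0.56 in the model and did not pass in the 12 libraries alone. Cholesterol synthesis genes gave 6 lower of 19 (7 adjusted over the list alone), none kept in the 12 libraries, with adjusted p = 0.308 with an estimated correlation. Neutrophil genes gave 5 higher of 12 (8 adjusted over the list alone, 1 in the 12 libraries alone), with adjusted p = 0.327 with an estimated correlation. DAM genes gave 1 higher of 28 and cytokine and NF-kB genes 7 of 20 (13 adjusted over the list alone), with adjusted p = 0.904 and 0.35 with an estimated correlation.

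Between genotypes under cuprizone (6 KO against 4 Het) 2576 genes passed (1502 higher, 1074 lower, or 1050 and 1401 with DESeq2's size factors), against 1104 planned and 900 (317 and 583) in the 10 libraries alone, where 41 of 67 named genes kept their call. Lox (3.51 ± 0.51), Atf5 (2.80 ± 0.41, adjusted p = 1.5e-06) and mt-Atp6 (2.57 ± 0.44) rose, and Klf4 (-4.35 ± 0.46, adjusted p = 9.36e-10), Fosb (-4.24 ± 0.66), Klf2 (-3.89 ± 0.53), Gem (-3.76 ± 0.53) and Fos (-3.56 ± 0.64) fell. Of dissociation stress genes 16 of 18 fell (17 adjusted over the list alone, 11 in the 10 libraries alone), and camera's call held with an estimated correlation in the model (adjusted p = 0.0454). It did not hold in the 10 libraries alone. ATF4 genes split, with 13 higher and 4 lower of 28 (the same adjusted over the list alone). Psat1 of serine synthesis rose by 1.90 ± 0.29 while Atf4 itself fell (-1 ± 0.18), with adjusted p = 0.336 with an estimated correlation. Glycolysis genes gave 14 higher of 18, such as Pgk1 (1.52 ± 0.24), mitochondrial DNA genes 11 of 13, complex I genes 23 of 36 and complex III 8 of 15, against 11, 4, 4 and 1 in the 10 libraries alone, each with adjusted p = 0.132 with an estimated correlation. In KO replicate 3 the mean log2 CPM of mitochondrial DNA genes was 7.83, inside the Het range (7.382 to 8.413), against 9.143 to 9.81 in the other KO libraries. DAM genes gave 7 higher and 3 lower of 28, among them the cathepsins Ctsb (1.11 ± 0.15) and Ctsd (0.89 ± 0.15) and the chemokine Ccl6 (-1.24 ± 0.24), and 11 of 21 lysosome genes rose, such as Tpp1 (0.76 ± 0.11), with adjusted p = 0.743 and 0.248 with an estimated correlation. The inflammasome sensor Nlrp3 (-1.40 ± 0.23) and Insig1 of sterol control (-1.55 ± 0.18) fell.

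The difference of the cuprizone effect between genotypes gave 33 genes (11 higher, 22 lower), against 13 planned and 1 in the 23 libraries alone. Without Het cuprizone replicate 4 the model gave 19. The 1 gene in the 23 libraries was the chaperone Hsp90aa1 (-1.54 ± 0.28, adjusted p = 0.00487), which rose in Het (1.90 ± 0.20) under cuprizone. Gpnmb, Apoe and the DAM list did not pass this test, so the response of DAM genes was not shown to differ between KO and Het.

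Depletion was compared with naive mice inside the ncRNA-poor batch (6 against 9 control libraries). The calls were 1469 (749 higher, 720 lower), against 1573 planned and 2239 in the 15 libraries alone. Without Het depletion replicate 2, which held both Xist (29.3 CPM) and Y-linked counts (85.3 CPM), the count was 618. Lyve1 of border macrophages (-4.50 ± 0.60), H2-Eb1 (-4.12 ± 0.45), H2-Aa (-3.89 ± 0.42, adjusted p = 2.26e-09), Mgl2 (-3.69 ± 0.50) and H2-Ab1 (-3.44 ± 0.38) fell. The sulphotransferase Chst2 (2.92 ± 0.25, adjusted p = 1.8e-12), Gpr162 (2.44 ± 0.25), Rn7s1 (2.28 ± 0.42), Dsp (2.26 ± 0.46) and Ift80 (2.21 ± 0.49) rose. All 12 border macrophage genes fell, such as Mrc1 (-3.10 ± 0.44), and 15 of 21 lysosome genes rose (17 adjusted over the list alone), such as Ctsl (1.05 ± 0.12), both with camera calls that held at adjusted p = 0.00524 with an estimated correlation. DAM genes gave 19 higher and 1 lower of 28 (21 and 2 adjusted over the list alone), such as the tetraspanin Cd63 (1.48 ± 0.15) and Itgax (1.71 ± 0.22), and complex I genes 17 of 36 (30 adjusted over the list alone), each with adjusted p = 0.0515 with an estimated correlation. Of homeostatic genes 8 fell and 1 rose of 19, with the ADP receptor P2ry12 by -0.71 ± 0.09 and Tmem119 by -0.61 ± 0.10, and endothelial genes gave 6 lower of 11, with adjusted p = 0.214 and 0.0515 with an estimated correlation. Antigen presentation genes went both ways (4 higher, 5 lower of 15), with median 0.03 but mean -1.13.

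In KO mice (2 against 5 libraries) 237 genes passed (114 higher, 123 lower, or 141 and 126 with DESeq2's size factors), against 373 planned and 38 in the 7 libraries alone. Of 32 named genes 9 kept their call in the 7 libraries and 5 with each library left out in turn. The count was 68 and 84 without KO depletion replicates 2 and 1. Chst2 (2.73 ± 0.35), the lectins Clec7a (2.53 ± 0.39) and Lgals3 (2.01 ± 0.38) and AF529169 (2.91 ± 0.41) rose, the cytokine receptor Il7r fell (-2.92 ± 0.39), and each passed in the 7 libraries too. Lox rose by 3.01 ± 0.49 in the model alone. Homeostatic genes gave 5 lower of 19 (14 adjusted over the list alone), such as Slc2a5 (-1.12 ± 0.21), with a camera call that held (adjusted p = 0.0182 with an estimated correlation). Cell cycle genes, with 0 calls of 38 (8 lower adjusted over the list alone) and a median of -1.43, kept theirs (adjusted p = 0.016). Neither held in the 7 libraries alone.

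At depletion KO differed from controls (2 against 6 libraries) in 316 genes (203 higher, 113 lower), against 51 planned and 310 in the 8 libraries alone. Of 27 named genes 23 kept their call in the 8 libraries and 5 with each library left out in turn. Lox (4.12 ± 0.51), Atf5 (3.18 ± 0.38, adjusted p = 4.06e-07), Mthfd2 (2.40 ± 0.39), Gmppb (2 ± 0.40) and Clec7a (1.91 ± 0.39) rose, and Klhdc8b (-2.63 ± 0.64), Gpr165 (-2.51 ± 0.53), Mycl (-2.46 ± 0.55), Il7r (-2.40 ± 0.38) and Tmem176a (-2.34 ± 0.35) fell. Of ATF4 genes 8 of 28 rose (12 adjusted over the list alone), such as Trib3 (4.48 ± 0.75), and of homeostatic genes 4 of 19 fell (11 adjusted over the list alone), such as Sparc (-0.73 ± 0.15), with both camera calls held (adjusted p = 0.0143 and 0.0368 with an estimated correlation). Neither held in the 8 libraries alone (adjusted p = 0.0747 for both). Neutrophil genes had a median of 4.06 with 0 of 12 past (9 higher adjusted over the list alone) and adjusted p = 0.413 with an estimated correlation. Their mean log2 CPM was 2.574 in KO replicate 2, -1.221 in KO replicate 1 and -1.169 to 0.14 in the 6 control libraries. Mitochondrial DNA genes gave 3 higher of 13 (8 adjusted over the list alone), mt-Co1 first (1.46 ± 0.28), with adjusted p = 0.16 with an estimated correlation. With 2 KO libraries the count rested on each: 68 without replicate 2 and 28 without replicate 1. The count was 210 and 206 without Het replicates 1 and 2.

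Repopulated control microglia differed from naive ones (8 against 9 libraries) in 1752 genes (983 higher, 769 lower), against 2249 planned and 3132 in the 17 libraries alone. H2-Q7 (3.32 ± 0.28) and H2-Q6 (3.07 ± 0.22, adjusted p = 9.64e-16), near-identical class I genes whose reads could be split between copies, rose, with St8sia1 (2.6 ± 0.44), Ms4a4c (2.07 ± 0.50) and the interferon-induced Ifi27l2a (2.07 ± 0.23). H2-Eb1 (-4.51 ± 0.36), H2-Aa (-4.43 ± 0.35), Cd163 (-4.23 ± 0.44), Mrc1 (-3.93 ± 0.37) and F13a1 (-3.71 ± 0.38) fell. Of interferon genes 20 of 22 rose (21 adjusted over the list alone), such as Ifit2 (1.70 ± 0.14), Ifi204 (1.82 ± 0.16) and Ifit3 (1.61 ± 0.16), with a camera call that held (adjusted p = 0.000165 with an estimated correlation). Border macrophage genes gave 12 lower of 12, lysosome genes 12 higher of 21 (15 adjusted over the list alone), such as Ctss (0.91 ± 0.10), and endothelial genes 9 lower of 11 (11), all with calls that held (adjusted p = 0.000686, 0.0429 and 0.0317). In the 17 libraries alone these 4 list calls were lost with an estimated correlation (adjusted p = 0.0651 for interferon and 0.0557 for border macrophage genes). DAM genes gave 13 higher and 3 lower of 28 (20 and 4 adjusted over the list alone), such as the receptor Axl (1.90 ± 0.19), with adjusted p = 0.199 with an estimated correlation. The proliferation marker Mki67 fell (-1.11 ± 0.33), with 3 of 38 cell cycle genes lower and adjusted p = 0.199 with an estimated correlation. Antigen presentation genes went both ways (7 higher, 5 lower of 15), with median 0.13 but mean -0.84.

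KO microglia after repopulation (4 against 5 naive libraries) changed in 564 genes (372 higher, 192 lower), against 3918 planned and 591 in the 9 libraries alone. Without KO naive replicate 1 the count was 375. Lox (2.41 ± 0.43), Tnfsf8 (2.16 ± 0.26), Ifi27l2a (2.15 ± 0.31, adjusted p = 7.67e-06) and Cox6a2 (2.12 ± 0.41) rose, and Cd163 (-3.50 ± 0.60), H2-Eb1 (-3.44 ± 0.49), H2-Aa (-3.35 ± 0.47), F13a1 (-3.13 ± 0.52) and Cd74 (-3.05 ± 0.39) fell. Interferon genes gave 8 higher of 22 (17 adjusted over the list alone), border macrophage genes 10 lower of 12 (12) and ATF4 genes 8 higher of 28 (14 and 1 lower), with camera calls that held (adjusted p = 0.00496, 0.00496 and 0.0127 with an estimated correlation). Of these the interferon call held in the 9 libraries alone. The ATF4 rise is widened by KO naive replicate 1, with a mean log2 CPM of 3.911 where the other naive KO libraries held 4.751 to 5.396 and repopulated KO 5.28 to 5.657. Apoe fell (-1.79 ± 0.34).

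Repopulated KO differed from repopulated controls (4 against 8 libraries) in 1374 genes (738 higher, 636 lower, or 620 and 772 with DESeq2's size factors), against 483 planned and 2345 in the 12 libraries alone, where 52 of 53 named genes kept their call. Atf5 (3.97 ± 0.29, adjusted p = 6.93e-15), Aldh1l2 (3.56 ± 0.39), Cox6a2 (3.48 ± 0.36), Lox (3.28 ± 0.38) and Mthfd2 (2.66 ± 0.29) rose. The complement gene Cfb (-2.65 ± 0.86), Klhdc8b (-2.54 ± 0.45), Il7r (-2.48 ± 0.27), the chemokine Ccl9 (-2.30 ± 0.27) and Ipcef1 (-2.17 ± 0.37) fell. Of ATF4 genes 22 of 28 rose (22 adjusted over the list alone), such as Trib3 (5.94 ± 0.58), Slc7a5 (1.84 ± 0.16) and Phgdh (1.61 ± 0.15), and camera's call held (adjusted p = 7.7e-06 with an estimated correlation). Glycolysis genes gave 8 higher of 18 (11 adjusted over the list alone), such as Gpi1 (0.73 ± 0.15), cell cycle genes 6 higher of 38 (15 and 1 lower), such as Mki67 (1.47 ± 0.40) and Top2a (1.40 ± 0.40), and interferon genes 7 lower of 22 (9), such as Oas1a (-1.22 ± 0.27), each with adjusted p = 0.123 with an estimated correlation. Homeostatic genes gave 5 lower and 1 higher of 19 (8 and 1), such as Selplg (-1.13 ± 0.12) and Olfml3 (-0.71 ± 0.10), with adjusted p = 0.378 with an estimated correlation. DAM genes split (4 higher, 4 lower of 28), with Axl at -1.17 ± 0.25 and Clec7a at 1.27 ± 0.29.

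The difference of the repopulation effect between KO and controls gave 17 genes (7 higher, 10 lower, or 9 and 21 with DESeq2's size factors), against 4 planned and 103 in the 26 libraries alone. Without KO naive replicate 4 the count was 29. Pde2a (1.58 ± 0.32), Tgfbi (1.09 ± 0.19), Slc7a5 (1.09 ± 0.23), S1pr1 (1.01 ± 0.19) and Edem1 (0.51 ± 0.11) were higher, and Lag3 (-1.79 ± 0.24, adjusted p = 8.44e-06), Il7r (-1.79 ± 0.32), Ccl9 (-1.72 ± 0.33), Slamf8 (-1.71 ± 0.22) and Cep152 (-0.98 ± 0.19) lower. ATF4 genes, with median 0.46 and 1 of 28 past (6 adjusted over the list alone), kept camera's call in the model (adjusted p = 0.0223 with an estimated correlation). It was lost in the 26 libraries alone. KO naive replicate 1, with an ATF4 mean log2 CPM of 3.911 against 4.751 to 5.396 in KO naive 2 to 5, lowers the naive KO side of this test. The cell cycle list did not pass.

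From depletion to repopulation 1243 genes changed in controls (8 against 6 libraries, 817 higher and 426 lower), against 476 planned and 1570 in the 14 libraries alone, and 582 in the model without Het depletion replicate 2, the library with both Xist and Y-linked counts. H2-Q7 (2.66 ± 0.34), the receptor Hcar2 (2.50 ± 0.37), Egr2 (2.30 ± 0.53), Ifi27l2a (2.30 ± 0.28) and Axl (2.30 ± 0.24) rose, and Lgals3 (-2.27 ± 0.28), the phosphodiesterase Pde2a (-1.75 ± 0.21), Baiap2 (-1.64 ± 0.30) and the sterol exporter Abca1 (-1.01 ± 0.11) fell. Of interferon genes 21 of 22 rose (22 adjusted over the list alone) and of cholesterol efflux genes 4 of 13 fell (5), with camera calls that held (adjusted p = 4.93e-05 and 0.0163 with an estimated correlation). The efflux call was lost in the 14 libraries alone (adjusted p = 0.0925). Cytokine and NF-kB genes gave 10 higher of 20 (11) and homeostatic genes 6 higher of 19 (7), such as Tmem119 (0.69 ± 0.10) and P2ry12 (0.51 ± 0.09), with adjusted p = 0.266 and 0.425 with an estimated correlation. In KO (4 against 2 libraries) 167 genes passed (86 higher, 81 lower, or 78 and 110 with DESeq2's size factors), against 24 planned and 471 in the 6 libraries alone. The count was 42 and 35 without KO depletion replicates 1 and 2 and 101 without KO repopulation 3. Epha2 (2.33 ± 0.42), Htra3 (2.12 ± 0.41) and Ccnd1 (1.75 ± 0.34), a cyclin of cell cycle entry, rose and Lgals3 (-2.34 ± 0.41) and Chst2 (-2.22 ± 0.38) fell.

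Age was compared in Het mice (3 old against the 2 deep adult libraries). The model over all libraries called 988 genes (574 higher, 414 lower), the planned fit 2513 and the 5 libraries alone 10 (10 higher), with 0 of 54 named genes kept, so the calls below rest on the spread of other libraries. Old replicate 3 held counts of both Xist (702 CPM) and Y-linked genes (28.6 CPM), and without it 447 genes were called. Leaving out 1 library gave 352 to 1352 genes. The count was 570 without old replicate 1 and 352 and 365 without adult 12 and 13. Gpnmb (10.08 ± 1.12, adjusted p = 7.23e-09), the elastase Mmp12 (7.75 ± 1.13), the secreted Spp1 (6.83 ± 0.83), Ahnak2 (6.75 ± 0.85) and the lipoprotein receptor Olr1 (6.42 ± 1.46) rose. Rn7s6 (-8.15 ± 1.08), Gpr165 (-3.17 ± 0.50), Hba-a2 (-2.93 ± 0.92), Pecam1 (-2.21 ± 0.44) and Uqcc1 (-2.11 ± 0.63) fell. Some markers of other cells were lower in mean log2 CPM in every old library than in adult 12 and 13. These were red blood cell (0.934 to 1.386 against 3.611 to 3.859), endothelial (2.045 to 2.197 against 2.559 to 3.694) and neutrophil genes (0.37 to 1.198 against 1.432 to 3.123). For the other lists of other cells the ranges overlapped. Of DAM genes 25 of 28 rose (26 adjusted over the list alone), such as Itgax (4.47 ± 0.47), Clec7a (5.44 ± 0.59) and Lgals3 (5.44 ± 0.57), and of homeostatic genes 16 of 19 fell (18), such as Olfml3 (-1.17 ± 0.14), Slc2a5 (-1.48 ± 0.21) and Tmem119 (-1.12 ± 0.16). Cholesterol synthesis genes gave 4 higher of 19 (10 adjusted over the list alone) and interferon genes 7 of 22 (13), such as Ifit2 (1.64 ± 0.27), and these 4 camera calls held (adjusted p = 0.00019, 0.000445, 0.0123 and 0.041 with an estimated correlation). In the 5 libraries alone none of them held. Mitochondrial DNA genes gave 9 higher of 13 (12) and glycolysis genes 7 of 18 (10), such as Pkm (1.65 ± 0.28), with adjusted p = 0.0672 and 0.146 with an estimated correlation.

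**Figure D3:**
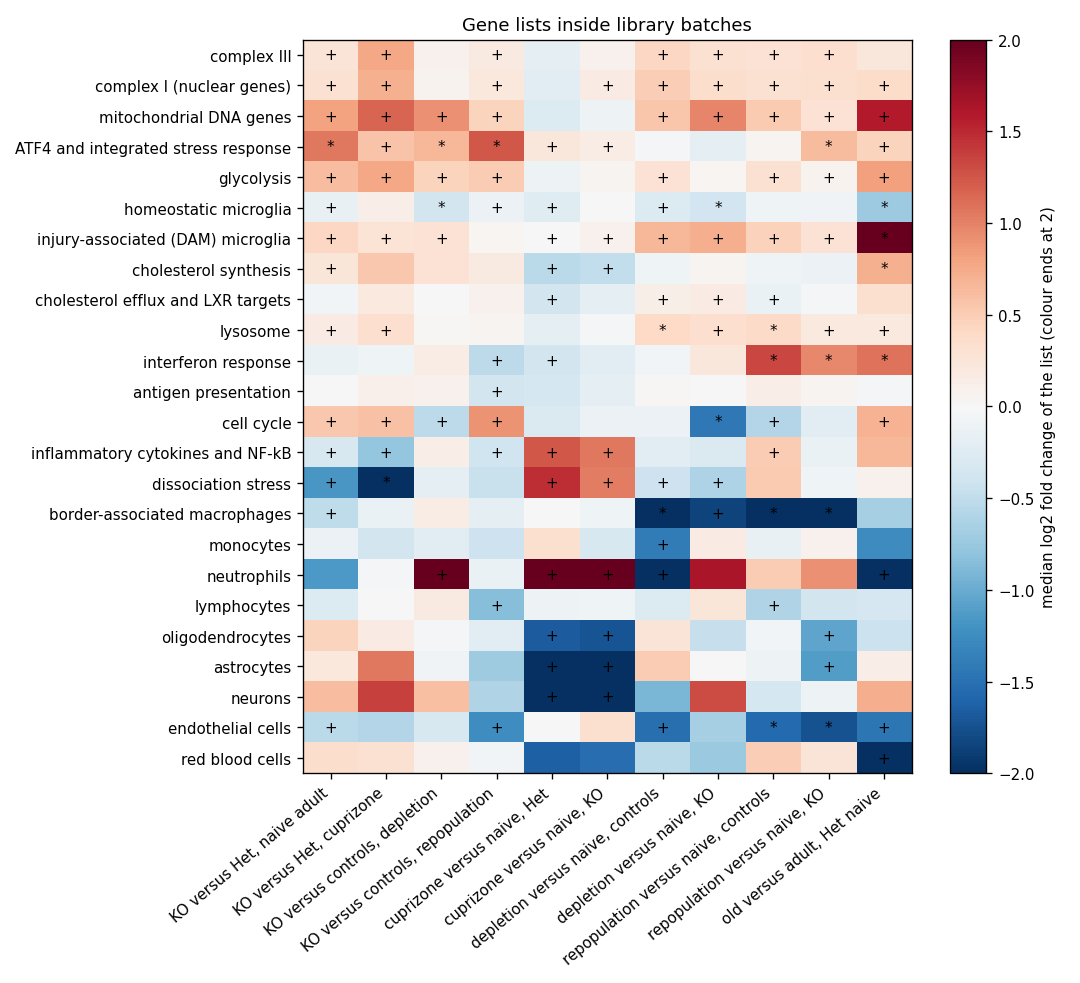
Median log2 fold change (within batch) of the gene lists in each comparison, where * marks a camera call kept with an estimated correlation and + a camera call lost with it. ATF4 genes have medians of 1.05 in naive KO against Het and 1.24 in repopulated KO against controls, both marked *.

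KO was compared with Het or controls 5 times without a shared library: naive ncRNA-rich, naive ncRNA-poor, cuprizone, depletion and repopulation. In all 5, 98 genes were higher (0.00113 by independent lists) and 25 lower (0.000211). The 5 lists come from 1 fit that shares the spread of each gene, so the counts for independent lists are no test. The 98 include Atf5, Mthfd2, Asns, Chac1, Gdf15, Nupr1, Slc7a5, Lox, Hif1a, Gpi1 and mt-Co1, and 54 of the 97 ribosomal protein genes measured. The medians of the ribosomal protein genes lay between 0.61 and 1.31 over the 5 comparisons, and reads of these genes could be shared with pseudogenes. The 25 include Uqcrfs1, Gpr165, Tmem176a, Tmem176b, Cebpd, Siglece, Gimap6 and Clec4a3. Genes other than list members were chosen here after their values were seen.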

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

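The tests of library batch and of handling below and the splits of KO against Het naive with batches pooled were chosen after the result was seen. The batches behind the within-batch splits, and the fits with sex and with thinned counts, were chosen after the counts were examined, with the bounds of their tests set before their own results.

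Some libraries stood apart from the rest of their group of 4 to 10. Of 182 groups and measures tested 11 had such a library, where chance gives about 1 in 20. Mean log2 CPM of antigen presentation genes was 6.651 in Het cuprizone replicate 4 (others 6.17 to 6.229), and that of mitochondrial DNA genes 7.83 in KO cuprizone replicate 3 (others 9.143 to 9.81). In repopulated KO, border macrophage genes were at 2.871 in replicate 4 (others 1.642 to 1.81), neutrophil genes at -1.034 in replicate 1 (others 1.253 to 1.514) and lymphocyte genes at -0.74 in replicate 3 (others -0.384 to -0.342). Endothelial genes were at 5.156 in WT depletion replicate 4 (others 3.387 to 3.674). In naive WT, border macrophage genes were at 6.415 in replicate 2 (others 5.265 to 5.532) and complex I genes at 4.573 in replicate 5 (others 4.799 to 4.83). Uqcrfs1 was at 35.9 CPM in Het repopulation replicate 4 (others 29 to 29.9). Total counts were 16.3 M in KO repopulation replicate 2 (others 12.6 to 13.1) and 15.6 M in WT naive replicate 3 (others 12.8 to 13.3).

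The effect of a treatment differed between KO and controls for named genes, each by a test of the difference itself. For cuprizone the naive libraries come from another depth batch than the cuprizone libraries in both genotypes, so a batch effect that differs by genotype cannot be told apart from these differences. They were, on the log2 scale, 1.88 (Umad1), 1.17 (Ppp2r1b), 1.04 (Psmd14), 1.02 (Cdc23), 0.77 (Tmem106b), -3.45 (Myh10), -2.01 (Ambra1), -1.54 (Hsp90aa1), -1.48 (Trim47) and -1.46 (Odc1), and Hsp90aa1 alone of these passed in the 23 libraries compared. For repopulation, within 1 batch, they were 1.58 (Pde2a), 1.09 (Tgfbi), 1.09 (Slc7a5), 1.01 (S1pr1), 0.51 (Edem1), -1.79 (Lag3), -1.79 (Il7r), -1.72 (Ccl9), -1.71 (Slamf8) and -0.98 (Cep152), all past the threshold in the 26 libraries compared, and 0.46 for the median of the ATF4 list, whose call was lost in the 26 libraries with an estimated correlation. The naive KO side of the ATF4 difference is lowered by KO naive replicate 1 (mean log2 CPM 3.911, KO naive 2 to 5 4.751 to 5.396). For depletion the differences were 1.22 (Stk40) and, for the median of the cell cycle list, -1.29, with 0 of 38 members past (1 lower adjusted over the list alone). Stk40 did not pass in the libraries compared (adjusted p = 0.157). The cell cycle call held with an estimated correlation (adjusted p = 0.0246) and not with fry (adjusted p = 0.0701), and in the libraries compared with neither (adjusted p = 0.205 and 0.126). The test for depletion was added after the data were seen.

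The table also counts 2 transgenes that enter no comparison. CreERT2 reached 929 CPM in WT naive replicate 3 and was at 171 CPM or more in every library. tdTomato reached 347 CPM in KO naive replicate 5, and was at 0 in Het cuprizone replicate 4, old Het replicate 1 and KO cuprizone replicate 1, where a count of 0 allows up to 0.831, 0.125 and 0.851 CPM by counting error alone. It was at 0.142 and 0.198 CPM in Het naive replicates 8 and 11 and at 3.07 CPM in KO naive replicate 7, and at 36.6 CPM or more in every other library. No library without these transgenes is named by the labels.

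Het against WT in naive mice, all batches pooled, called 6699 genes. Among the 18 naive Het and WT libraries alone the count was 4199, and 6574 with sex as a covariate, which argues against sex as the whole cause. Inside the ncRNA-poor batch 4 genes were called, so library batch is a likely source of the pooled count. A difference between Het and WT too small for 4 against 5 libraries stays open. The count inside that batch was 117 without WT replicate 5, where genotype follows sample order and the 2 cannot be told apart.

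Dissociation stress genes were lower in KO in some comparisons. The call held with an estimated correlation under cuprizone (adjusted p = 0.0454), though not in the 10 libraries alone (adjusted p = 0.236), and was lost in naive KO against Het (adjusted p = 0.0771). Against WT the median was 0.38 with 0 of 18 past. Under cuprizone the median in KO against Het was -2.01 with sex in the model, which argues against sex. With counts thinned to 1 depth that median was -2.14. The cuprizone libraries held only 2.7 to 5.1 M before thinning, so this argues against depth within that range alone. The median was -0.18 in naive KO against Het in the ncRNA-poor batch and -2 in the ncRNA-rich middle batch. Batch or handling may therefore set how far these genes fall. The -0.18 mixes genotype with sample order, in which Het 1 to 4 stand apart from KO 1 to 4. The mean log2 CPM was 6.016 to 7.573 in KO 1 to 4, against 6.268 to 7.077 in WT 1 to 4. It was 8.487 in KO 5, which stands with Het 1 to 4 and WT 5 (7.551 to 7.737). In a test of the difference between the 2 batches 4 of 18 genes passed (13 adjusted over the list alone). Camera's call (adjusted p = 7.91e-10) was lost with an estimated correlation (adjusted p = 0.551) and with fry (adjusted p = 0.261), so that difference stays open for the list as a whole. Across the 5 comparisons the medians were -1.65 (naive, ncRNA-rich), 0.10 (naive, ncRNA-poor), -2.08 (cuprizone), -0.19 (depletion) and -0.44 (repopulation). A weaker response of KO microglia to handling also stays open and was not tested.

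Mitochondrial DNA genes had higher medians in KO. The medians of the 5 comparisons that share no library were 1.16, 0.51, 1.16, 0.91 and 0.45, with 12, 3, 11, 3 and 3 of 13 genes past. With an estimated correlation camera's call held in the naive ncRNA-rich comparison (adjusted p = 0.0389) and was lost in the others (adjusted p = 0.229, 0.132, 0.16 and 0.449), in naive KO against Het over all batches (adjusted p = 0.0565) and against WT (adjusted p = 0.137, 2 of 13 past). The lowest of the 5 medians was 0.45 (repopulation, all ncRNA-poor), past the bound set against library batch. Each comparison was made inside its batches, so an uneven mix of these batches between KO and controls cannot give these medians. They cannot show whether batch sets the size of the difference. A test of the difference between the ncRNA-poor and middle batches gave a median of -0.77 with 0 of 13 past (3 lower adjusted over the list alone), and camera's call (adjusted p = 0.000118) was lost with an estimated correlation (adjusted p = 0.551), so a part set by batch stays open. DESeq2's size factors (1.08) under cuprizone argue against scaling. Thinned counts (1.11) argue against depth only within the 2.7 to 5.1 M of the cuprizone libraries. That the loss of RISP raises these transcripts is a hypothesis, found and tested on the same data, which may hold in the naive ncRNA-rich libraries and stays open in the others.

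Groups were compared with 100 splits of the same libraries, the real one included, refitting only those libraries. The bound was under 5 splits as large, without a correction for the number of comparisons. Within batches the real split called the most genes for KO against Het naive (2429 genes, highest other 44, 1 split as large) and under cuprizone (900, 4, 1). It did so for depletion in controls (2239, 5, 1) and for repopulation in controls (3132, 554, 1) and KO (591, 376, 1). The same held for KO against controls at repopulation (2345, 5, 1) and repopulation against depletion in controls (1570, 125, 1). Being first of 100 splits argues against a chance draw for each on its own. It cannot exclude chance over all comparisons, since no correction was made for their number. KO against WT (154, 344; 2) and the repopulation interaction (103, 526; 2) met the bound too. There another split of the same libraries called more genes than the real one, so chance was not excluded. For cuprizone against middle-depth naive libraries in Het (343, 3, 1) and KO (66, 2, 1) the real split was also first. Batch could not be excluded there, since the depth batch is the treatment. Chance could not be excluded for Het against WT (0 genes by edgeR with 2587 at an unadjusted p under 0.05, highest other 1680; 100 splits as large, as any count reaches 0) or the cuprizone interaction (1, highest other 1; 9 splits).

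For the repopulation interaction another split called more genes within 1 batch, so its pooled counts of 4 and 1 (1 split as large) do not exclude chance. With batches pooled the real and highest other counts were 340 and 8 (cuprizone in Het, 1 split as large) and 1845 and 16 (repopulation in controls, 1), which argues against a chance draw for each on its own. They were 719 and 3916 (KO against Het naive; 3), 2905 and 3593 (KO against WT; 2), 4199 and 7030 (Het against WT; 2), 320 and 2947 (cuprizone in KO; 3), 848 and 5212 (depletion in controls; 2), 583 and 2251 (repopulation in KO; 3) and 1142 and 5004 (old against adult; 3). These met the bound on splits as large, but another split called more genes in each, so chance was not excluded. For the cuprizone interaction they were 0 and 578 (100 splits as large), where chance could not be excluded, with 1026 genes at an unadjusted p under 0.05 and 104 called by DESeq2. Several of the highest splits parted the libraries along the ncRNA batches, as with 5 ncRNA-rich libraries of 13 on 1 side and 12 of 13 on the other in KO against Het, and point to that structure. These splits move libraries across batches, so they bear on a chance draw of libraries and cannot exclude batch. In Het against WT the real groups are themselves parted by batch, with 9 of 13 Het and 0 of 5 WT libraries ncRNA-rich, and 0 genes passed in the libraries compared within 1 batch. Within batches the counts are those above, and 10 for old against adult (3 against 2 libraries, no splits drawn).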

How the results depend on the processing

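The fits within batches, on only the libraries compared, with sex, with thinned counts, with the replicate block and library batch together and in single batches were chosen after the result was seen, as was leaving out libraries within batches.

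Of the named genes with the largest changes none reversed under the alternatives run on them, which are given next, or with 1 library left out. Of 180 named values within batches 179 kept their side of the threshold with DESeq2's size factors (Trib3 in KO repopulation did not), 172 with sex in the model, 134 with thinned counts, 138 on only the libraries compared and 124 in the planned fit. With list members counted too, the named genes that kept their call in the libraries compared, and with each library of groups or batches of 2 to 5 left out in turn, were 72 and 70 of 73 (KO against Het naive), 16 and 12 of 30 (KO against WT), 0 and 1 of 3 (Het against WT), 27 and 34 of 57 (cuprizone in Het), 10 of 41 (cuprizone in KO, none left out), 41 and 54 of 67 (KO against Het, cuprizone), 1 and 3 of 10 (its interaction), 61 and 33 of 62 and 9 and 5 of 32 (depletion in controls and KO), 23 and 5 of 27 (KO at depletion), 61 and 54 of 62 and 34 and 26 of 41 (repopulation in controls and KO), 52 and 35 of 53 (KO at repopulation), 10 and 8 of 10 (its interaction), 49 and 28 of 52 and 23 and 2 of 24 (repopulation against depletion, controls and KO) and 0 and 26 of 54 (old). Uqcrfs1 in naive KO against Het stayed between -1.93 and -2.20 over 8 settings. The cause of a changed count below was not tested, except that thinning removes counts and a left-out library removes a sample.

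Of 197 planned list calls 14 held with an estimated correlation. Within batches 30 of 187 held with it, 6 of these also in the libraries compared alone, and fry called 119 lists, 113 of them among the 187. Camera itself kept 182 of the 187 with DESeq2's size factors, 180 with sex in the model, 165 with thinned counts, 171 on only the libraries compared and 144 in the planned fit, where oligodendrocyte genes reversed for repopulation in KO (median -1.05 within batches, adjusted p = 0.0018, and 0.22 planned, adjusted p = 0.0175; neither held with an estimated correlation). The cause was not tested. With DESeq2's size factors 6 list medians near 0 changed sign, all without a camera call, such as antigen presentation in KO against Het naive (0.01 to -0.03) and DAM genes in KO at repopulation (0.04 to -0.01). The same scaling turned the balance of higher and lower calls within batches from 1699 and 1407 to 1428 and 1696 (KO against Het naive), 641 and 1061 to 812 and 739 (cuprizone in Het), 1502 and 1074 to 1050 and 1401 (KO against Het, cuprizone), 114 and 123 to 141 and 126 (depletion in KO), 738 and 636 to 620 and 772 (KO at repopulation) and 86 and 81 to 78 and 110 (repopulation against depletion, KO).

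Library batch in the model moved the planned counts of KO against Het naive from 1760 to 3106, KO against WT from 5291 to 356, Het against WT from 6699 to 4, cuprizone in KO from 2293 to 1037, KO against Het under cuprizone from 1104 to 2576, its interaction from 13 to 33, depletion in KO from 373 to 237, KO at depletion from 51 to 316, repopulation in KO from 3918 to 564, KO at repopulation from 483 to 1374, its interaction from 4 to 17, repopulation against depletion from 476 to 1243 (controls) and 24 to 167 (KO), and old against adult from 2513 to 988.

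With 2 surrogate variables these were 2753 (KO against Het), 577 (KO against WT), 3 (Het against WT), 2364 (KO against Het, cuprizone), 193 (its interaction), 303 (KO at depletion), 770 (repopulation in KO), 1434 (KO at repopulation), 61 (its interaction), 1225 and 157 (repopulation against depletion, controls and KO) and 1598 (old). With only the groups compared and batches pooled they were 719, 2905, 4199, 340 (cuprizone in Het), 320 (in KO), 0 (cuprizone interaction; edgeR, 1026 at an unadjusted p under 0.05), 848 and 21 (depletion, controls and KO), 310 (KO at depletion), 583 (repopulation in KO), 2345 (KO at repopulation), 1570 and 471 (repopulation against depletion) and 1142 (old).

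DESeq2 gave 104 for the cuprizone interaction, 2613 and 1888 for depletion in controls and KO, 129 for KO at depletion, 823 for KO at repopulation, 50 for its interaction, and 716 and 104 for repopulation against depletion. Its size factors in edgeR gave 25 for the cuprizone interaction, and 30 for the repopulation interaction within batches. Without the filter the counts were 1428 (cuprizone in Het), 699 (KO against Het, cuprizone), 219 (depletion in KO), 24 (KO at depletion), 281 (KO at repopulation), 2 (its interaction) and 8 (repopulation against depletion, KO).

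The replicate number was used as a block, though the numbers were not shown to pair samples. It gave 2813, 481 and 207 for the naive comparisons, 8883 and 8482 for cuprizone in Het and KO, 3021 for KO against Het under cuprizone and 201 for its interaction. It gave 224 for KO at depletion, 1427 and 537 for repopulation in controls and KO, 1032 for KO at repopulation and 8 for its interaction. For repopulation against depletion it gave 860 and 97, and for old 7473. Together with library batch the block moved the within-batch counts of Het against WT from 4 to 96, of cuprizone from 1702 to 875 (Het) and 1037 to 378 (KO) and of its interaction from 33 to 60, and left the other 12 within 1.5 times. Old and adult share no replicate number, so that comparison has no estimate there.

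Depth limits the number of calls. Thinned to the smallest total, the within-batch counts were 1336, 149 and 1 (naive: KO against Het, KO against WT, Het against WT), 376 and 93 (cuprizone in Het and KO), 900 (KO against Het, cuprizone), 4 (its interaction), 615 and 94 (depletion), 151 (KO at depletion), 876 and 268 (repopulation), 552 (KO at repopulation), 6 (its interaction), and 513 and 50 (repopulation against depletion). Sex in the model left 2 genes for Het against WT. KO against Het gave 502 in the ncRNA-poor and 105 in the deep batch.

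On only the libraries compared the within-batch counts moved to 154 (KO against WT), 0 (Het against WT; edgeR, 2587 at an unadjusted p under 0.05), 343 and 66 (cuprizone in Het and KO), 900 (KO against Het, cuprizone), 1 (its interaction), 2239 and 38 (depletion), 3132 (repopulation in controls), 2345 (KO at repopulation), 103 (its interaction), 471 (repopulation against depletion, KO) and 10 (old).

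Leaving out 1 library moved planned counts as follows: cuprizone in Het to 928 to 1314 (each of the 4 Het cuprizone replicates), KO against Het under cuprizone to 721 to 982 (past 1.5 times without Het replicate 2 alone), its interaction to 4 to 35 (each Het replicate), depletion in controls to 327 to 1346 (327 without Het depletion replicate 2, 904 without 1), depletion in KO to 20 to 27 (either KO library), KO at depletion to 7 to 56 (7 without either KO, 8 and 13 without Het replicates 1 and 2), repopulation in KO to 1870 to 2344 and KO at repopulation to 248 to 432 (each KO repopulation library), repopulation interaction to 1 to 4 (1 without KO repopulation replicate 1, 2 without Het repopulation 3, WT repopulation 1 or 4, or WT naive 2, 3 or 5), repopulation against depletion to 175 to 428 in controls (175 and 306 without Het depletion replicates 2 and 1) and 2 to 6 in KO (each of the 6 libraries), and old to 1088 to 2198 (1088 without old replicate 3, 1147 without 1). A group left with 1 library is assumed to vary like the others.

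Within batches the ranges were 91 to 587 for KO against WT (587, 192, 91 and 192 without KO replicates 1, 3, 4 and 5, 222 and 228 without WT 3 and 4), 2 to 117 for Het against WT (117 without WT replicate 5, 2 without WT 1, 3 or 4), 19 to 40 for the cuprizone interaction (19 without Het cuprizone 4), 618 to 1462 for depletion in controls (618 without Het depletion 2), 68 to 262 in KO (68 and 84 without KO 2 and 1), 28 to 314 for KO at depletion (28 and 68 without KO 1 and 2, 210 and 206 without Het 1 and 2), 375 to 634 for repopulation in KO (375 without KO naive 1), 13 to 29 for the repopulation interaction (29 without KO naive 4), 582 to 1191 for repopulation against depletion in controls (582 without Het depletion 2) and 35 to 146 in KO (42 and 35 without KO depletion 1 and 2, 101 without KO repopulation 3), and 352 to 1352 for old (447 and 570 without old 3 and 1, 352 and 365 without adult 12 and 13).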

Other observations

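Tests in this part were chosen after the data were seen.

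Het old naive replicate 3 held 702 CPM of Xist, a transcript of the inactive X, together with 28.6 CPM over 4 Y-linked genes. The other old libraries held 0.168 and 1.35 CPM of Xist with 125 and 148 CPM of Y-linked genes. Het depletion replicate 2 held 29.3 CPM of Xist with 85.3 CPM of Y-linked genes, where other ncRNA-poor libraries held 0.603 to 14.1 CPM of Xist if male and 58.7 to 268 CPM if female by Y-linked genes. KO naive replicate 7 held 40.2 CPM with 168 CPM of Y-linked genes, against 0 to 0.992 CPM in the other male libraries of the middle batch. Without replicate 3 the within-batch comparison of old with adult called 447 genes, against 988 with it. Without Het depletion replicate 2 depletion in controls called 618 genes, against 1469, and repopulation against depletion 582, against 1243.

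Old Het libraries shared calls with KO. Of 574 genes higher in old and 383 higher in naive KO against controls in the ncRNA-poor batch 165 were shared, where 11.9 are expected of independent lists, and 84 of 414 and 246 lower ones (5.5 expected). The correlation of log2 fold changes was 0.091 across genes, which are not independent replicates. The old calls rest on the spread of other libraries.

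Mitochondrial ribosomal RNA took 9.78 to 26.33% of counts in old Het libraries. It took 5.24 to 8.78% in middle-depth and 6.13 to 8.23% in deep naive Het libraries, against 12.57 to 20.51% and 23.09 to 24.42% in KO. Under cuprizone it took 3.44 to 7.08% in Het and 8.53 to 15.02% in KO. In the ncRNA-poor libraries the KO ranges overlapped those of controls or lay below them: naive Het held 0.27 to 0.55%, WT 0.27 to 0.47% and KO 0.28 to 0.55%. At repopulation Het held 0.34 to 0.44%, WT 0.33 to 0.71% and KO 0.36 to 0.46%, and at depletion Het held 0.88 to 1.65%, WT 0.4 to 1.91% and KO 0.4 to 0.73%.

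Replicate numbers were checked as pairs. Of 66 pairs of groups that share at least 2 numbers 45 had 3 or more, and in 0 of these did every pair correlate above 0.1 (single correlations -0.435 to 0.731). Naive KO and Het, which gave both ends of that range, span several batches. Their correlations also show which libraries share a batch, so the check cannot decide on pairing there. Inside groups no library repeats another, and pairs between groups were not compared: over 216 pairs the lowest median chi-square per gene was 2.03, against 0.455 for 2 reads of 1 library, and the highest correlation was 0.979.

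Translation factor genes were counted beside ribosomal protein genes in the 5 comparisons of KO. Of 64 measured 8 were higher in all 5 and 0 lower in 4 or 5, with medians from 0.22 to 0.39.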
